A study of Arabidopsis thaliana with 6 samples.

How the data were processed

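Total RNA of whole 14-day-old plants was labelled with biotin through a whole-transcript kit and hybridized to Affymetrix arrays, 1 array per sample, per the labels' protocols. The deposited table held linear intensity values, 1 per probe set and array, made with Affymetrix Expression Console 1.3, per the submitters' processing notes. The summarization algorithm, the genome build and the annotation behind the deposited intensity values were not given in the sources used here. The 6 arrays had nearly equal quantiles, with medians of 28.8 to 29.2 and values from 1.5 to 14960.3, so the values were taken as normalized between arrays and were not normalized again. All columns of the table matched a sample by its label.

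The table had 38408 rows. Of these, 28501 were written to 1 decimal or fewer and were tested here as the non-control probe sets. The other 9907 carried more decimals and less even medians (10.1 to 12.7), and 33 of them appeared in the probe table. No source used here says what they are. They were left out before any test and fitted on their own as a check. Gene names came from the platform's probe table, updated by gene identifier through the RefSeq annotation of TAIR10.1, where 16574 of 16722 probe sets with 1 listed gene were found. Of the 28501 tested probe sets, 16704 (58.6%) named 1 gene, 744 named several and 11053 were not listed and stay unnamed here. The 16704 stood for 16542 genes, each represented by its probe set with the highest mean. In 542 rows the values were identical to those of another row, so some probe sets do not measure genes independently. No coordinates are given, because the build behind the table was not named.

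The intensity values were turned into log2 here; the floor of 1 set in advance touched no value. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance and no weights), two-sided, with Benjamini-Hochberg adjustment over 28501 probe sets and a threshold of 0.05. The fit had 4 residual and 3.31 prior degrees of freedom. Each SE and 95% interval comes from this moderated fit. On simulated data with the spread of the real probe sets and 200 of the 28501 changed, the fit recovered 24% of 1.5-fold, 78% of 2-fold, and 100% of 4-fold and 8-fold changes, with 5 false calls. With nothing changed it made 0 calls in limma and 1543 probe sets had an unadjusted p under 0.05. The simulated changes were placed on probe sets above the median intensity, and the simulated probe sets varied independently of each other. In the real data 3 probe sets passed, so the adjustment demanded a smaller unadjusted p than with 200 changed. The recovered shares therefore overstate what the real comparison could detect.

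Before the data were examined, 21 gene lists with 366 entries were fixed, 7 of them primary (starch synthesis, starch degradation, sucrose synthesis and cleavage, sugar transporters, sugar starvation, RAB5 and endosomal trafficking, flowering time). Members were matched by locus, which found 63 entries, and 1 entry was dropped because its symbol belongs to another locus. Lists were tested with camera at a preset correlation of 0.01, on 1 probe set per gene, adjusted over 12 lists. The minimum of 3 measured members for that test was set after the values had been seen. Counts of members are given over all probe sets and adjusted over the list alone. The adjustment over a list alone was made in each list separately, with no correction across the lists, so it is a weaker criterion.

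The genes named follow a rule fixed before the data were examined. ARA6 came first. Then, in each direction, came up to 12 genes past the threshold with separated groups, those with the largest change. With fewer than 5 such genes in a direction, as here, the rule took the 8 genes with the smallest p among those with separated groups and at least a 1.5-fold difference. Last, each list gave up to 4 members past the threshold, filled up to 2 with the smallest p. Probe sets without a gene name were not part of the rule. Probe set 13545569 and list members beyond those 2 were added after their values were seen.

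The alternatives set in advance left out the dimmest probe sets (mean log2 intensity under 3.52), normalized by quantiles again, centred arrays on their medians, let the prior variance follow intensity, dropped the moderation, weighted the arrays, took the replicate number as a block, left out each array in turn, and changed the threshold or the list test. Further alternatives were chosen after seeing the data: all 38408 rows, WT replicate 3 and ara6-1 replicate 1 left out together, the RAB5 list without ARA6, and the list test with an estimated correlation without each array.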

Results

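Transcript levels were measured with Affymetrix whole-transcript arrays in whole 14-day-old Arabidopsis thaliana plants of the Columbia accession. The arrays covered 3 biological replicates of the wild type (WT) and 3 of ara6-1, a knock-out mutant of ARA6. ARA6 is a plant-specific RAB5 GTPase, a small protein of endosomal membrane traffic, and the series asked how its loss bears on starch and sugar homeostasis. Plants had grown on MS plates at 23 °C in continuous light after 1 day at 4 °C. The values were linear probe set intensities, read here as log2, with array medians between 28.8 and 29.2 over 28501 probe sets. Precision was limited by the number of arrays, and p-values measured the spread between these samples, which the labels call biological replicates without saying how the plants were raised apart. WT replicate 3 and ara6-1 replicate 1 stood apart from the other arrays. Over probe sets above the median intensity, their deviations from their group means had SDs of 0.169 and 0.165 on the log2 scale. The other 4 had SDs of 0.120 to 0.126. The deviations of WT replicate 3 and ara6-1 replicate 1 correlated across the same probe sets at r = 0.289. Genes are not independent replicates in such a correlation.

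The ARA6 transcript itself (AT3G54840) was lower in all 3 mutant arrays. Its log2 intensity was 7.99, 8.40 and 8.34 in WT replicates 1 to 3 and 6.98, 7.15 and 6.89 in ara6-1 replicates 1 to 3. The group means were 8.24 ± 0.22 (SD, n = 3) and 7.01 ± 0.13 (SD, n = 3), a log2 fold change of -1.24 with an SE of 0.14 and a 95% interval of -1.56 to -0.91. The mutant level was thus 2.35-fold lower, and a signal remained. Over all 28501 probe sets the difference missed the threshold in limma with Benjamini-Hochberg adjustment (adjusted p = 0.140). Adjusted over the RAB5 list alone, it passed (limma, adjusted p = 1.373e-04), also without any of the 6 arrays in turn. With a prior variance that follows intensity, it passed over all probe sets as well (limma, adjusted p = 0.00615). Where the probes lie relative to the mutation was not analysed here, so the remaining signal does not tell how much intact transcript was left.

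The transcript that rose most among named genes in ara6-1 was QQS (AT3G30720, QUA-QUINE STARCH), a gene known to regulate leaf starch content. Its log2 intensity went from 3.76 ± 0.30 (SD, n = 3) in WT to 7.95 ± 0.06 (SD, n = 3) in the mutant, an 18.3-fold difference. The WT level of QQS lay at percentile 36.1 of all probe sets, without a detection call. The exact fold is therefore uncertain. Probe set 13545569, which had no gene name in the table used here and is given because it passed the test, rose from 5.33 ± 0.21 to 10.20 ± 0.10 (SD, n = 3 each), or 29.2-fold. AT3G60950 fell from 4.52 ± 0.38 to 1.88 ± 0.14 (SD, n = 3 each), down to the 9.75th percentile of all probe sets in the mutant. Its mutant intensities of 3.3 to 4 lay close to the 5th percentile of the arrays (2.9 to 3.2) and no detection measure was used. The size of the difference, 6.23-fold as fitted, is therefore uncertain and may be understated. These 3 probe sets, 2 higher and 1 lower, were the ones past an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment. In each of them the 3 mutant values lay outside the range of the 3 WT values. Since ara6-1 was the only mutant line measured, these arrays do not tell whether the 3 differences follow from the loss of ARA6.

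The log2 fold change of QQS was 4.19, with an SE of 0.16 and a 95% interval of 3.82 to 4.56 (limma, adjusted p = 2.081e-04). That of probe set 13545569 was 4.87, with an SE of 0.13 (limma, adjusted p = 4.174e-05). That of AT3G60950 was -2.64, with an SE of 0.19 (limma, adjusted p = 0.0165). QQS and probe set 13545569 passed without any single array. The call of AT3G60950 was lost without WT replicate 1 (adjusted p = 0.0668), WT replicate 3 (0.125), ara6-1 replicate 1 (0.129), ara6-1 replicate 2 (0.169) or ara6-1 replicate 3 (0.130) in limma, and in the fit on all 38408 rows (0.151), and it was not tested with probe sets under a mean log2 intensity of 3.52 left out. Its log2 fold change stayed between -2.49 and -2.70 in these fits. With WT replicate 3 and ara6-1 replicate 1 both left out, only probe set 13545569 still passed, and QQS had an adjusted p of 0.226 in limma with a log2 fold change of 4.25. The 3 calls became 16 with a prior variance that follows intensity, all 3 among them, and 0 with an unmoderated test, where 2556 probe sets had an unadjusted p under 0.05.

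**Figure D1:**
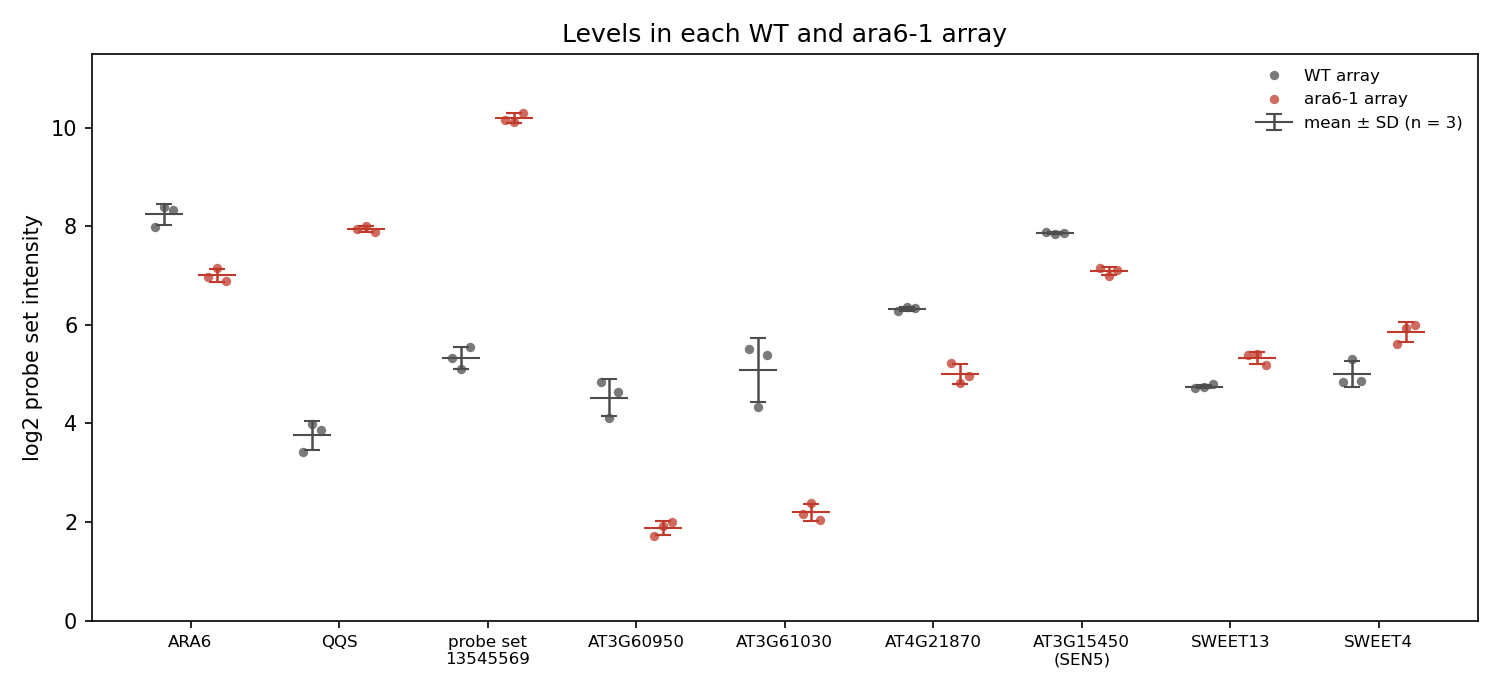
Log2 probe set intensity (vertical axis) of 8 named genes and probe set 13545569 in each array, with WT arrays in grey and ara6-1 arrays in red; points are arrays, horizontal marks are group means and bars are SDs (n = 3). QQS lies near 3.76 in WT and 7.95 in ara6-1, ARA6 near 8.24 and 7.01, and AT3G60950 and AT3G61030 end at 1.88 and 2.19 in the mutant.

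Other genes differed between the groups without passing the adjusted threshold. AT3G61030, separated from AT3G60950 by 18 genes in the TAIR10.1 annotation, had a log2 intensity of 5.08 ± 0.65 (SD, n = 3) in WT and 2.19 ± 0.17 (SD, n = 3) in ara6-1. Its mutant intensities, 4.1 to 5.2, were also near the low end of the arrays, so the size of its change is uncertain and may be understated. Its log2 fold change was -2.88 with an SE of 0.30 (limma, adjusted p = 0.119), and it passed without WT replicate 2 (limma, adjusted p = 0.00180). AT4G21870 had a log2 fold change of -1.33 with an SE of 0.12 (limma, adjusted p = 0.0717), and passed with probe sets under a mean log2 intensity of 3.52 left out (0.0407). AT3G15450 stood at 7.87 ± 0.03 in WT and 7.09 ± 0.08 in the mutant (SD, n = 3 each), a log2 fold change of -0.77 (limma, adjusted p = 0.168). Both AT4G15700 and AT1G06830, of the CC-type glutaredoxin family, were lower in all 3 mutant arrays, with log2 fold changes of -1.37 and -1.01 (limma, adjusted p = 0.435 and 0.423). AT1G05770 had a log2 fold change of -0.65 (limma, adjusted p = 0.316). With a prior variance that follows intensity, AT3G61030, AT4G21870 and AT3G15450 passed over all probe sets (limma, adjusted p = 0.00655, 0.00615 and 0.00655).

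Among genes with higher values in the mutant, AT1G66100 followed QQS. Its log2 intensity was 8.15 ± 0.16 (SD, n = 3) in WT and 9.24 ± 0.26 (SD, n = 3) in ara6-1, a log2 fold change of 1.09 with an SE of 0.16 (limma, adjusted p = 0.316), and it passed with a prior variance that follows intensity (0.0156). The other 6 of the 8 genes named in this direction had log2 fold changes between 0.62 and 0.76 and adjusted p between 0.423 and 0.447 in limma. They were AT5G55320 (0.76), AT2G48080 (0.73), AT5G38030 (0.72), AT5G67430 (0.71), scpl20 (AT4G12910, 0.71), a serine carboxypeptidase-like gene, and AT3G62780 (0.62). AT5G55320 had WT intensities of 3.3 to 3.6, close to the 5th percentile of the arrays, so the size of its difference is uncertain and may be understated. Over the whole array, 2569 probe sets had an unadjusted p under 0.05 in limma, 1034 higher and 1535 lower in the mutant. The nominal number by chance is 1425, and the simulated independent probe sets with nothing changed gave 1543. The 9 splits of the arrays that mix the genotypes gave 850 to 2171. The highest had WT replicates 1 and 3 and ara6-1 replicate 1 on the same side. These splits keep any genotype difference within their groups, so they are no clean reference for chance. In 4461 probe sets (15.7%) the groups did not overlap, against 10% by chance, and 276 of these differed at least 1.5-fold, 84 higher and 192 lower. An exact permutation test of 3 arrays against 3 could not give a two-sided p under 0.10 for any of them.

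Of the 7 measured transcripts of the starch synthesis and starch degradation lists, 0 passed the threshold in limma, over all probe sets or adjusted over the list alone. Measured here means found under a gene name, as 63 of the 366 list entries were. Of the 28501 tested probe sets, 11053 were not listed with a gene. Whether unmatched members are among them was not tested, so the measured members do not stand for their pathways. The starch synthesis list had 4 measured members of 19. The starch branching enzyme gene SBE2.2 (AT5G03650) stood at 8.62 ± 0.04 in WT and 8.84 ± 0.05 in ara6-1 (SD, n = 3 each), a log2 fold change of 0.22 (limma, adjusted p = 0.552), and passed adjusted over the list alone with a prior variance that follows intensity (limma, adjusted p = 0.0251). PTST (AT5G39790), which directs a starch synthase to the granule, had a log2 fold change of -0.14 (limma, adjusted p = 0.659). The list's median log2 fold change was 0.15 (camera, adjusted p = 0.402). The starch degradation list had 3 measured members of 24. Their log2 fold changes were 0.02 for the alpha-amylase gene AMY1 (AT4G25000; 95% interval -0.68 to 0.72), 0.02 for the disproportionating enzyme gene DPE1 (AT5G64860) and -0.01 for PWD (AT5G26570), and their median was 0.02 (camera, adjusted p = 0.855), where DPE1 and the median turned to -0.00571 after renewed quantile normalization. Of the sucrose synthesis and cleavage list, 2 members of 20 were measured and neither passed. They were SPS4F (AT4G10120), a sucrose phosphate synthase gene, with a log2 fold change of 0.12, and the invertase gene BFRUCT3 (AT1G62660), with 0.15.

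Among sugar transporters, SWEET13 (AT5G50800), a sucrose exporter gene, and SWEET4 (AT3G28007), a hexose transporter gene, were higher in all 3 mutant arrays. SWEET13 stood at 4.75 ± 0.04 in WT and 5.33 ± 0.13 in ara6-1, and SWEET4 at 5.0 ± 0.27 and 5.85 ± 0.21 (SD, n = 3 each). Their log2 fold changes were 0.58 with an SE of 0.10 and 0.85 with an SE of 0.17. Of the 14 measured members of the 28 listed, 0 passed over all probe sets in limma, and these 2 passed adjusted over the list alone (limma, adjusted p = 0.00875 for both), also without any of the 6 arrays in turn. The other 12 did not pass, 6 with positive and 6 with negative log2 fold changes, from -0.61 for SWEET3 (AT5G53190) to 0.24 for SWEET14 (AT4G25010). Both stood near the low end of the arrays, SWEET3 at a log2 intensity of 1.98 in ara6-1 and SWEET14 at 1.74 in WT and 1.98 in ara6-1, so the size of their differences is not determined. The list's median was 0.06 (camera, adjusted p = 0.355). The test for change in either direction gave a mixed p of 5.339e-04 in fry, which does not compare the list with other genes. It was not particular to this list. Unadjusted mixed p values in fry were 5.042e-04 for sugar starvation, 0.00351 for RAB5 and endosomal trafficking and 0.0288 for starch synthesis. They were above 0.05 for the other tested lists.

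Among genes known to respond to sugar starvation, AT3G15450 (listed as SEN5), a transcript of darkened and sugar-starved leaves, and AKINBETA1 (AT5G21170), a subunit gene of the SnRK1 kinase, were lower in all 3 mutant arrays. AKINBETA1 stood at 8.72 ± 0.08 in WT and 8.42 ± 0.12 in ara6-1 (SD, n = 3 each), a log2 fold change of -0.30 with an SE of 0.11. Of the 4 measured members of the 20 listed, 0 passed over all probe sets in limma, and these 2 passed adjusted over the list alone (limma, adjusted p = 2.278e-04 for SEN5 and 0.0474 for AKINBETA1). The call of AKINBETA1 was lost without WT replicate 1 (limma, adjusted p = 0.120), WT replicate 2 (0.0597), WT replicate 3 (0.0844), ara6-1 replicate 2 (0.111) or ara6-1 replicate 3 (0.138). The other 2 members did not pass, MCCB (AT4G34030) with a log2 fold change of 0.22 and ATL8 (AT1G76410), near the low end of the arrays in both groups, with -0.05. The list's median was -0.18 (camera, adjusted p = 0.342, and adjusted p = 0.529 with an estimated correlation).

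The RAB5 and endosomal trafficking list had 4 measured members of 24. ARA6 was the member that passed adjusted over the list alone. The other 3 did not pass, with log2 fold changes of 0.21 for CCZ1A (AT1G16020), 0.16 for MON1 (AT2G28390) and -0.04 for CCZ1B (AT1G80910), genes of the complex that hands endosomes from RAB5 to RAB7. The list's median was 0.06, while its mean was -0.23 and camera's direction was down (adjusted p = 0.682). Without ARA6 the median was 0.16, the mean 0.11 and the direction up (camera, adjusted p = 0.339). The flowering time list had 3 measured members of 23, all with positive log2 fold changes and none past either threshold. They were GIGANTEA (GI, AT1G22770) with 0.28, and the floral repressor genes SNZ (AT2G39250) with 0.17 and SMZ (AT3G54990) with 0.08 (camera, adjusted p = 0.342, and adjusted p = 0.529 with an estimated correlation).

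**Figure D2:**
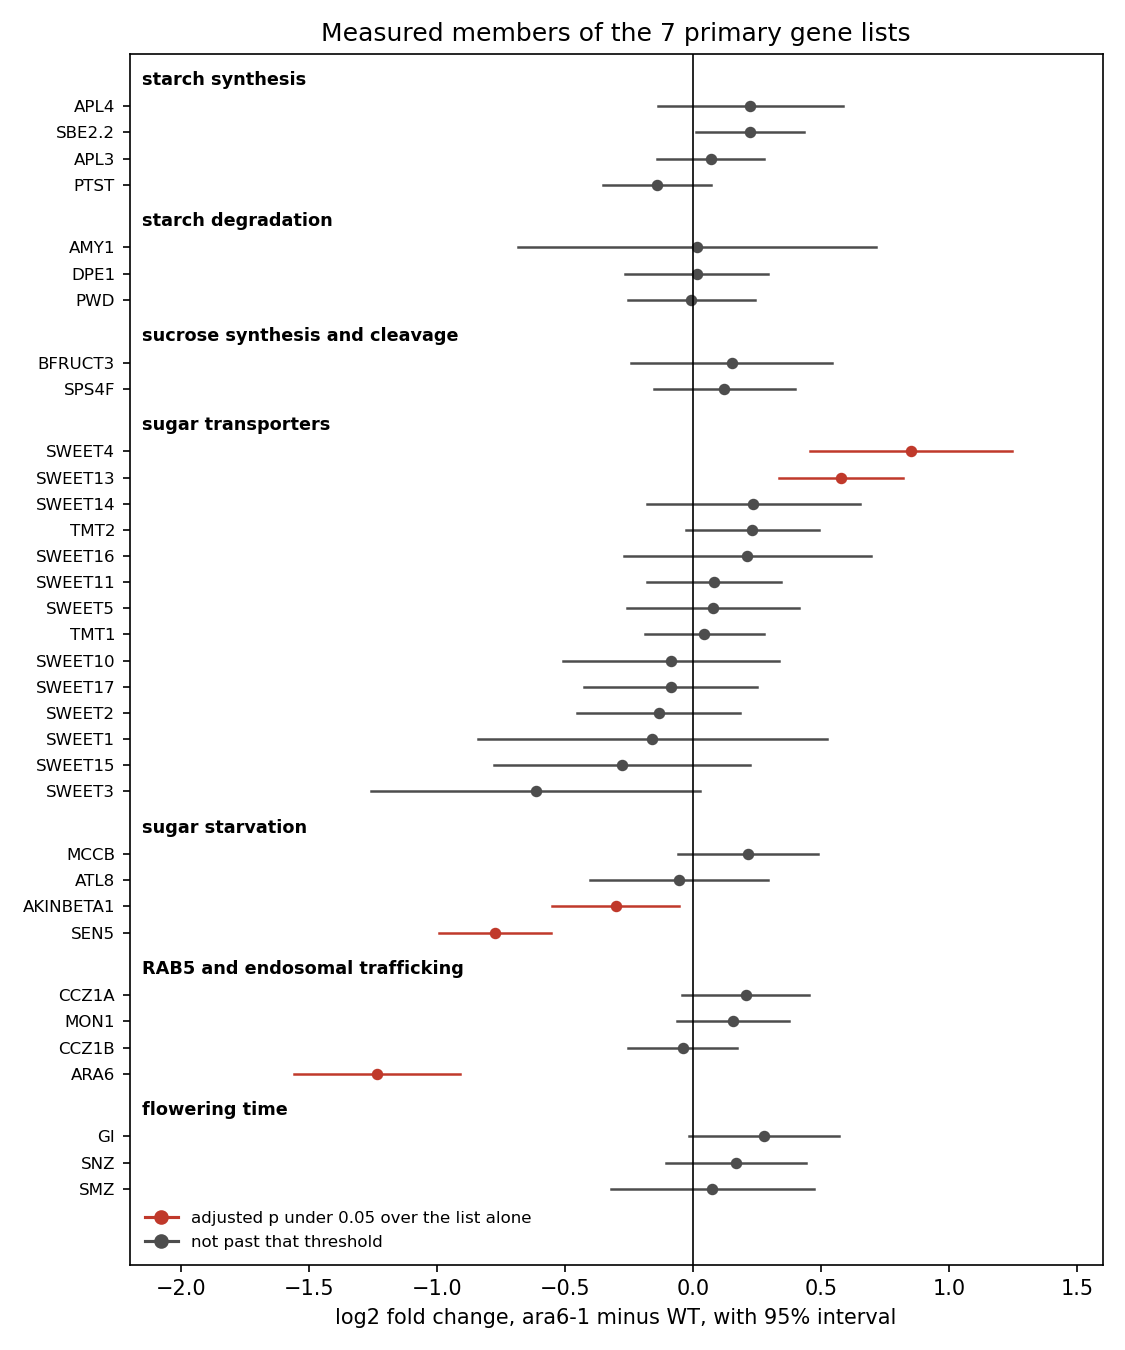
Log2 fold change, ara6-1 minus WT (horizontal axis), of the measured members of the 7 primary gene lists, with 95% intervals from limma (n = 3 arrays per group); red marks an adjusted p under 0.05 over the list alone and grey the rest. SWEET4 (0.85) and SWEET13 (0.58) lie above 0, and ARA6 (-1.24), SEN5 (-0.77) and AKINBETA1 (-0.30) lie below it.

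The other lists held responses and tissues found in whole plants, and 0 of their members passed over all probe sets or adjusted over the list alone in limma. The anthocyanin and flavonoid list (5 of 20 measured) had a median log2 fold change of -0.19, with -0.40 for DFR (AT5G42800) and -0.19 for UF3GT (AT5G54060) (camera, adjusted p = 0.447). The cold, drought and ABA list (6 of 19 measured) had a median of 0.15, with 0.25 for each of COR15A (AT2G42540) and COR15B (AT2G42530) (camera, adjusted p = 0.447). Both medians moved with single arrays. Without ara6-1 replicate 1, an array that stood apart, the anthocyanin median was -0.40 and the cold median 0.30, each past the threshold (camera, adjusted p = 0.0476) but not with an estimated correlation (adjusted p = 0.504 with an estimated correlation for both). Without WT replicate 3 the medians were 0.00625 and -0.0114, and without ara6-1 replicate 2 they were 0.00244 and 0.0114. COR15A and COR15B had log2 fold changes of 0.49 and 0.47 without ara6-1 replicate 1, both past the threshold adjusted over the list alone (limma, adjusted p = 0.0460), and of 0.07 and 0.06 without ara6-1 replicate 2. The photosynthesis list (4 of 22 measured) had a median of 0.08, with 0.17 for LHCB4.1 (AT5G01530) and 0.08 for SBPASE (AT3G55800) (camera, adjusted p = 0.402). The circadian clock list (3 of 18 measured) had a median of 0.06 (camera, adjusted p = 0.402), with 0.28 for GI and 0.06 for COR28 (AT4G33980).

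Root markers (3 of 16 measured) had a median log2 fold change of 0.10, with 0.11 for PYK10 (AT3G09260, listed as BGLU23) and 0.10 for EXPA7 (AT1G12560) (camera, adjusted p = 0.478). Commonly used reference genes (3 of 8 measured) had a median of -0.11, with -0.18 for PEX4 (AT5G25760, listed as UBC21) and 0.12 for GAPC2 (AT1G13440) (camera, adjusted p = 0.682). The jasmonate and wounding list held 2 measured members of 23, THI2.1 (AT1G72260) with -0.46 and PDF1.2 (AT5G44420) with 0.18, whose SD within ara6-1 was 1.68. THI2.1 passed adjusted over its list alone without WT replicate 3 (limma, adjusted p = 0.0271) or without ara6-1 replicate 2 (0.0211), and with a prior variance that follows intensity (0.0312). The heat shock and unfolded protein list held 1 member of 13, BZIP60 (AT1G42990) with -0.33. With 1 member, the p over its list alone is limma's unadjusted p, which was 0.0548, and 0.0114 without ara6-1 replicate 1, 0.0182 without that array and WT replicate 3, and 0.0463 with a prior variance that follows intensity. Over all probe sets BZIP60 passed in none of the alternatives (limma, adjusted p between 0.353 and 0.835). The salicylic acid list held 1 member of 20, SAG101 (AT5G14930) with 0.14, and the cell wall list 1 of 13, EXPA8 (AT2G40610) with 0.03. The lists for nitrate response, phosphate starvation, leaf senescence and floral organs had 0 members measured under a gene name. No list passed camera's test over the 12 lists with at least 3 measured members, where the smallest adjusted p was 0.342, nor with an estimated correlation, where it was an adjusted p of 0.529.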

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

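Chosen after seeing the data were the fits on all rows, without WT replicate 3 and ara6-1 replicate 1, the RAB5 list without ARA6, and the estimated-correlation list tests without each array. The count of 3 probe sets past the threshold stayed between 2 and 4 with the dimmest probe sets left out, renewed quantile normalization, median centring, array weights, all rows, a 1.5-fold minimum, an adjusted p under 0.1, or any single array left out. Leaving out the dimmest removed AT3G60950, and AT4G21870 took its place. It was 16 with an intensity trend (5 higher, 11 lower), 0 with the unmoderated test in limma (2556 with an unadjusted p under 0.05), 1 without both arrays, and 46 at an unadjusted p with at least a 2-fold change. ARA6 kept its direction throughout, with adjusted p between 0.00615 and 0.722 over these alternatives, and passed with the trend alone (log2 fold change -1.24). With the trend, 2 list members passed over all probe sets and 8 adjusted over the list alone, against 0 and 5; the latter count ran from 4 to 8 with 1 array left out (8 without ara6-1 replicate 1). The cause was not tested.

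Values near 0 turned direction. Renewed quantile normalization gave -0.00571 for DPE1 and for the starch degradation median. Array weights gave -0.0621 for PDF1.2. Leaving out both arrays gave -0.27 for PDF1.2 and -0.0825 for EXPA8. With 1 array left out, medians ran from -0.0680 to 0.0494 for starch degradation, from -0.40 to 0.00625 for anthocyanin, from -0.0114 to 0.30 for cold and from -0.00948 to 0.15 for the clock. Single genes ran from -0.17 to 0.35 for AMY1, from -0.0680 to 0.0835 for DPE1, from -0.69 to 0.98 for PDF1.2, from -0.23 to 0.18 for EXPA8, and from -0.00948 to 0.12 for AT4G33980 (COR28). Over all alternatives, named genes kept direction and call in 637 values, lost the call in 12, gained it in 8 and turned in 16. The lists kept both in 171 values, gained a call in 2 and turned in 8. Without ARA6, the RAB5 list's median moved from 0.06 to 0.16 and its mean from -0.23 to 0.11, still not past the threshold.

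The arrays showed no clear pairing by replicate number. Same-numbered arrays deviated together at r = -0.20, 0.17 and -0.15 across probe sets above the median intensity. WT replicates 1 and 3 correlated best with another number, and WT replicate 2 with its own. Deviations within a group are tied to each other through the group mean. These r values are therefore not independent and do not exclude pairing. With the replicate block, 2 probe sets passed, both among the 3, and AT3G60950 did not (adjusted p = 0.176). No measure of signal over background was used here, so dim probe sets carry no detection call.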

Other observations

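Of the tests below, the splits of the arrays, the adjusted-p test around ARA6 and the root marker test were planned; the others were chosen after the results were seen. The CC-type glutaredoxins, small redox proteins, were looked at as a list. AT4G15700, AT1G06830 and AT2G30540 prompted the list, with log2 fold changes of -1.37, -1.01 and -0.60, and 16 of the other 17 listed loci were measured. Of these 16, 14 had negative log2 fold changes, 5 with an unadjusted p under 0.05 in limma, with a median of -0.33 and examples of -0.54 for AT5G18600, -0.57 for AT3G62950 and -0.51 for AT2G47870. Some members lay near the low end of the arrays, where the sign of a difference counts for little. Examples are GRX480, at a log2 intensity of 1.61 in WT and 1.47 in ara6-1, and ROXY1, at 1.91 and 1.89. AT3G62950 was also dim, at 2.68 in ara6-1, while AT5G18600 was brighter, at 5.92. No member passed the adjusted threshold over all probe sets. The shift of the 16 had a camera p of 7.057e-04, and a p of 0.0221 with an estimated correlation. These, and the p values given for this family below, are unadjusted. The family was chosen from these same data, so they are not an independent test of it. Without WT replicate 3 and ara6-1 replicate 1 the median was -0.33.

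Whether the glutaredoxin family moves as a whole stays open. Random lists matched on intensity had medians from -0.15 to 0.10 in their middle 95%, and the median of -0.33 lies below them, which argues against a general shift at that intensity for the 16. AT4G15660 to AT4G15690 neighbour AT4G15700 and may share probes with it. Without those 4, the remaining 12 had a median of -0.11, within the range of their random lists (-0.17 to 0.11), a camera p of 0.0189 and a p of 0.0687 with an estimated correlation. The random lists thus give no argument against a general shift for these 12, and the contrast for the 16 leans on the 4. With AT3G18460, a locus first tested with the others and then taken off the list, the p values were 9.704e-04 and 0.0322. A response of these genes to the loss of ARA6 was not tested apart from these explanations.

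The 3 probe sets past the threshold set the arrays of the 2 genotypes apart, and the highest count in any of the other splits of the 6 arrays was 0. The real split was thus 1 of 10 with a count as large, and 10 splits are too few for a share under 0.05. A segment of another accession carried along with ARA6 is a candidate explanation for some differences. The planned test decides nothing, since 0 genes near ARA6 passed and the odds ratio had an upper 95% bound of 256. By unadjusted p, 31 of 338 named genes within 1 megabase of ARA6 in TAIR10.1 were under 0.05 against 1421 of 16203 elsewhere, an odds ratio of 1.05 (95% interval 0.699 to 1.53), which argues against a broad effect. A different share of root tissue cannot be told apart for small differences. Of 16 root markers, 3 were measured, with a median of 0.10 and an SD of 0.0773 over the markers. The 95% interval of their mean difference over the arrays, added after the result was seen, ran from -0.14 to 0.26. It holds the 0.2 that the explanation needs. The log2 fold changes of QQS (4.19), probe set 13545569 (4.87) and AT3G60950 (-2.64) lay far outside that interval. For these 3 the values argue against a different root share. The mutation itself remains an open explanation.

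AT3G60950 and AT3G61030 were both low in ara6-1, AT3G60950 past the threshold in the planned test and AT3G61030 with the intensity trend, and they lie close together on the chromosome that carries ARA6. A deletion spanning both may be proposed, but AT3G60980 and AT3G61010, the genes between them measured above the median intensity, had log2 fold changes of -0.07 and -0.08, with a median of -0.0754, against the fall of at least 1 that a deletion needs. All 6 measured named genes between the pair had negative log2 fold changes, from -0.54 to -0.07, each with a 95% interval that held 0. The rest of the 6 were dimmer and decide little. AT3G60980 itself lay at percentile 52.9 of all probe sets in WT, without a detection call. The case against a deletion thus rests mainly on AT3G61010, at percentile 69.2. From ARA6 to AT3G61030 the odds ratio of an unadjusted p under 0.05 was 1.11 (95% interval 0.772 to 1.55), which argues against a segment rich in differences. Probes shared between the pair could make them 1 observation: without probe sequences this cannot be told apart, and the difference of -0.24 between their log2 fold changes does not bear on it, since both mutant levels lie near the low end of the arrays. Changes at each gene alone, genetic or regulatory, were not tested.

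Among 59 families of at least 5 genes sharing a symbol stem, none shifted with an estimated correlation (smallest adjusted p = 0.919), while the calmodulin-like CML genes had a median of -0.30 and an adjusted p of 0.0337 with camera's preset correlation. With the intensity trend, AT2G45180 (log2 fold change -0.62) and AT7SL-1 (-0.86), a signal recognition particle RNA gene, also passed (limma, adjusted p = 0.0470 for both). The 9907 rows outside the tested probe sets gave 0 calls in limma on their own, with 517 at an unadjusted p under 0.05 and a smallest adjusted p of 0.801.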
